A study of Mus musculus with 16 samples.

How the data were processed

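Livers of male C57BL/6 mice that were fed a high-fat diet alone (HF) or a high-fat diet with betaine (HB) for 8 weeks, up to an age of 16 weeks, were measured in 3 ways. These were total polyadenylated mRNA, mRNA bound to ribosomes with nascent chains (ribosome-bound mRNA), and RNA fragments pulled down with an antibody against N6-methyladenosine (m6A). The labels list 16 samples, and 12 of them were analysed here, 2 for each diet and kind of library. The m6A input samples were not analysed here. Per the labels, each sample pooled material from independent experiments, so the spread between samples and every p-value below measure only how these pools differed, not how single mice differed.

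Per the labels, the mRNA and ribosome-bound libraries were sequenced and alignment was against RefSeq transcripts. The deposited read count is the number of reads per gene, with splice variants of a gene merged, and the authors applied no normalization to it. The deposited RPKM is, per the file headers, the read count per kilobase of the longest transcript, scaled to the library's reads; in each library it equalled the read count divided by that length and by 1 library total slightly above the sum of the counts. For the m6A libraries, reads were trimmed with Trimmomatic 0.36 and aligned with TopHat 2.0.13, per the labels' protocols. The submitters' processing notes also list cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.6.0, MACS2 2.1.0.20151222, HOMER 4.8 and edgeR for the mm10 build, without saying which step used which tool. The deposited m6A peaks were called per library and give, per the file headers, a start, an end, a pileup signal at the summit, the −log10 of the p-value and of the q-value, and a fold enrichment (a ratio over the local background). The scaling of the pileup is not stated. Every deposited fold enrichment was at least 6.00, so the authors' peak lists had been filtered on it.

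Read counts of the 24539 genes in each table were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. The planned model had 4 group means (diet by kind of library), TMM scaling, genes kept by filterByExpr (12634 genes), a quasi-likelihood F test for each contrast, and Benjamini-Hochberg adjustment with a threshold of 0.05. Contrasts were HB against HF in mRNA, HB against HF in ribosome-bound mRNA, ribosome-bound over total mRNA within each diet, and the change of that ratio with diet (the interaction, here called translation ratio). The model, the contrasts, the fixed gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. One step departs from the plan: the 2 HB ribosome-bound libraries differed little more than repeated reads of 1 library would (given in the report), so their counts were summed and the model had 7 libraries and 3 residual degrees of freedom. CPM values are library-scaled counts (edgeR cpm) after TMM scaling of these 7 libraries. The HB ribosome-bound group then has a single value, which the model assumes to vary like the other groups. With an HF ribosome-bound library also left out, no ribosome-bound group has a replicate. The spread of such fits comes from the mRNA libraries alone, so their counts and list calls do not allow for the spread of ribosome-bound mRNA.

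A fit of the 4 mRNA libraries alone (12817 genes, 2 residual degrees of freedom) was among the alternatives chosen before the data were examined. That it carries the wording was decided after both fits had been seen. Both mRNA fits are reported, because the common dispersion was 0.464 in the 7 libraries and 0.0644 in the 4 mRNA libraries. The words rose and fell are used for mRNAs only where the fit of the 4 mRNA libraries passed the threshold.

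Of 35 gene lists written from general knowledge, those with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast. Camera with an estimated correlation and fry, whose PValue asks if a list's genes move one way on balance, were alternatives. Named genes followed this rule. For each HB against HF contrast, they were the 10 genes with the largest change in each direction among those that passed the threshold, had a mean of at least 5 CPM, and, for mRNA and ribosome-bound mRNA, had all HB values on 1 side of the HF values. Where fewer than 5 passed in a direction, genes with the smallest p made up 5, as values only. For the ratio in HF they were the 5 highest and 5 lowest. From each list up to 4 called members with the largest change were taken, or up to 2 with the smallest p, as values only, if none was called. The rule also always named Bhmt, Gnmt, Mat1a, Pemt, Mettl3, Mettl14, Wtap, Fto, Alkbh5, Ythdf1, Ythdf2, Ythdf3, Fasn, Srebf1, Ppara and Cyp7a1. For m6A it took the 5 genes of each diet-specific peak set with the highest enrichment, and up to 10 genes that were in such a set and called. The text gives the ones that matter and summarises the rest. A gene that the rule would name is not reported here, and nothing was put in its place. A fold against a group with 0 reads is a lower bound against a floor of 3 reads per library, which was 0.459 CPM for HF and 0.184 CPM for HB ribosome-bound mRNA. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

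Peaks were compared with bedtools 2.31.1 by an overlap of at least 1 bp. By their summit they were placed in gene spans of the RefSeq annotation of GRCm38.p6, the build called mm10. Each peak was assigned to the protein-coding genes whose span held its summit, and to other gene types only where no protein-coding span did. Peaks moved at random within their gene span, in 20 draws, gave a level for comparison. As it spreads peaks over introns too, it is too low as a chance level for peaks that keep to exons. With 2 libraries per diet the 4 m6A libraries can be split in 3 ways, so the smallest exact permutation p is 0.333 and no test between diets was made on peaks. Only gene spans of this annotation were at hand here, without exons, strands or the genome sequence, so positions within transcripts and sequence motifs were left out.

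The code was tested on simulated counts over 12634 genes, with 100 genes changed 2-fold and 100 changed 4-fold. They had the libraries' means and sizes and 1 dispersion per kind (0.0644 for mRNA, 2.28 for ribosome-bound mRNA). Few real ribosome-bound counts lay just above 0: HF replicate 1 held 139 genes with 1 to 5 reads and 864 with 21 to 50. The simulation was not made to copy this. Calling 0 unchanged genes in a simulated ratio therefore does not show that counts in the real ratios are controlled. The fit of the 4 mRNA libraries called 8 of the 2-fold and 89 of the 4-fold genes, and 3 unchanged genes. The 7-library fit called 0 of either in the mRNA contrast, 0 of either in the translation ratio and 0 of either in the ratio in HF, with 0 unchanged genes called in each. In the ribosome-bound contrast it called 7 and 5 of them and 736 unchanged genes, so its counts there are not controlled at this spread. On the same simulated counts, limma voom with quality weights per fraction called 0 changed and 0 unchanged genes in the ribosome-bound contrast, and DESeq2 1.42.0 called 4389 unchanged genes there and 3229 in the translation ratio. A fit of the simulated ribosome-bound libraries alone called 0. In simulated mRNA counts with 1 list raised 1.5-fold, camera with the preset correlation called that list and 0 others in both mRNA fits. With an estimated correlation its adjusted p was 0.608 in the 7 libraries and 0.214 in the 4, and fry also called 0 lists. At this number of libraries those tests thus missed a 1.5-fold change. Simulated genes were drawn independently, whereas the correlation estimated in the 7 real libraries was 0.310 for cholesterol synthesis and 0.311 for fatty acid synthesis. The simulation therefore cannot tell whether the preset correlation holds for such lists, nor why the other tests miss larger changes.

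Alternatives to each result were other scalings (DESeq2 size factors, total counts), DESeq2 for the test, other filters, the replicate number as a block, limma on log2(RPKM + 0.1) and log2(RPKM + 1), a fold threshold, only the libraries compared, each library left out in turn, stricter peak lists and overlaps, and some added later; the closing section gives their effect.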

Results

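Livers of 2 diet groups of mice, HF (high-fat diet) and HB (high-fat diet with betaine, a methyl donor), were compared in total mRNA, ribosome-bound mRNA and m6A, with 2 libraries per diet and kind. The mRNA libraries held 11437462 and 11570775 reads in HF and 22492813 and 18011999 in HB. The ribosome-bound libraries held 5778439 and 6431510 reads in HF and 6508500 and 8659310 in HB. The m6A libraries held 22060 and 24141 peaks in HF and 22086 and 25718 in HB. The mRNA libraries detected 14981 to 15556 genes, and the ribosome-bound libraries 8313 to 9374.

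The HB ribosome-bound libraries were much closer to each other than any other pair. Over 9160 genes their counts differed by a chi-square of 1.40 per degree of freedom, against 99.1 in the HF ribosome-bound pair, 36.9 in the HF mRNA pair and 105 in the HB mRNA pair. A value of 1.40 was still above sampling noise (chi-square p = 3.78e-130). No gene had 0 reads in 1 HB ribosome-bound library and over 20 in the other, whereas 1689 and 1109 genes did so, in either direction, in the HF pair. The counts of the HB pair were therefore summed and counted as 1 sample. Of 7922 genes with at least 10 CPM in mRNA, 15.0% and 11.5% had 0 reads in the HF ribosome-bound libraries, and 9.23% and 8.94% in the HB ones.

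**Figure D1:**
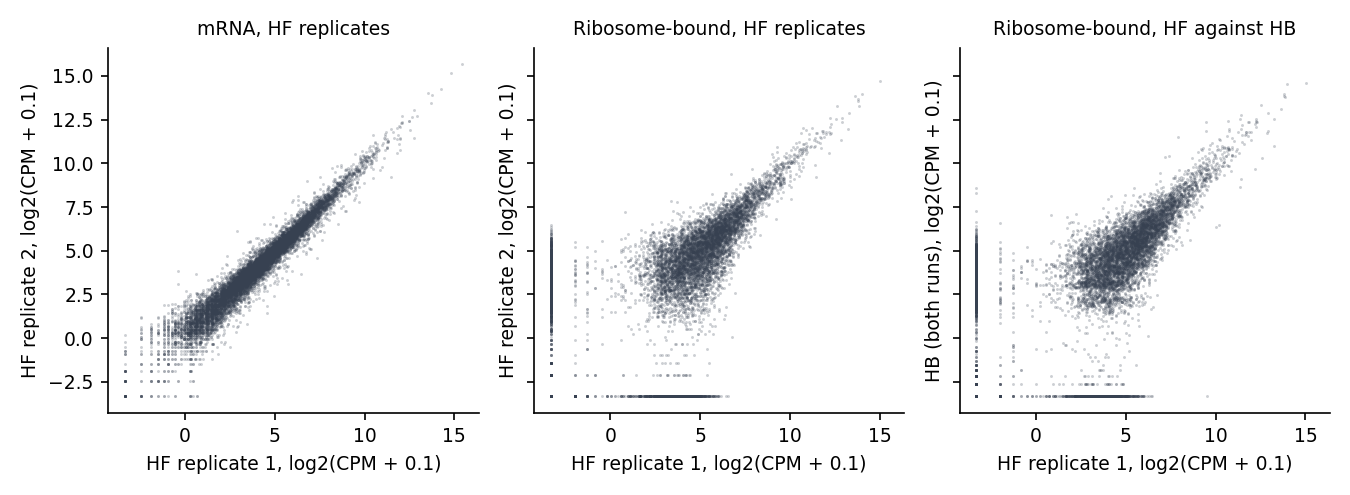
Each point is 1 gene, with log2(CPM + 0.1) of 1 library on each axis, for the HF mRNA replicates, the HF ribosome-bound replicates, and HF replicate 1 against the summed HB ribosome-bound libraries. Points along the axes of the ribosome-bound panels are genes with no reads in 1 library, 1689 and 1109 of which had over 20 reads in the other HF replicate.

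The first comparison asked which liver mRNAs change when betaine is added to the high-fat diet. Enzymes of cholesterol synthesis rose in HB. Among them were Fdps and Idi1, which make isoprenoid precursors, Sqle, which makes squalene epoxide, and Cyp51, which demethylates lanosterol. Fatty acid synthesis rose with them, in Fasn, the fatty acid synthase, Me1, which supplies NADPH, and Fads2, a desaturase. So did Plin2, which coats lipid droplets, and Sdha, Sdhd, Cox5a and Atp5b of the respiratory chain. Of the enzymes that handle methyl groups, Gnmt, which uses S-adenosylmethionine to methylate glycine, and Pemt, which methylates phosphatidylethanolamine, rose, while Bhmt, which takes the methyl group from betaine itself, was not called.

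In the edgeR fit of the 4 mRNA libraries, 2740 of 12817 genes passed an adjusted p of 0.05, 1446 higher and 1294 lower in HB, and 2431 of them changed at least 2-fold. In the planned 7-library fit 0 of 12634 genes passed, with 1647 at an unadjusted p under 0.05 and a smallest adjusted p of 0.210. On those 7 libraries DESeq2 called 1133 genes, limma voom with quality weights per fraction 881, and limma on log2(RPKM + 0.1) 0, with 1921 at an unadjusted p under 0.05. The 7-library count was 2695 without HF ribosome-bound replicate 1 and 2705 without HF ribosome-bound replicate 2. Those fits without an HF ribosome-bound library took their spread from the mRNA libraries alone, since no ribosome-bound group then had a replicate. The log2 changes of the 4-library and 7-library edgeR fits had the same sign for 12372 of 12444 genes. Leaving out an mRNA library gave 776 calls without HF replicate 1, 1539 without HF replicate 2, 787 without HB replicate 1 and 3024 without HB replicate 2. With total counts in place of TMM the median of all genes shifted by -0.29 on the log2 scale, and 783 genes were then called higher and 2320 lower.

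Fdps (chromosome 3, 89093588 to 89101967, GRCm38.p6) went from 33.2 ± 5.24 CPM in HF to 318 ± 175 CPM in HB (SD, n = 2), a log2 change of 3.24 (SE 0.41, adjusted p = 0.00403). Fasn (chromosome 11, 120805958 to 120825166) went from 183 ± 47.3 to 1447 ± 1482 CPM, a log2 change of 2.96 (adjusted p = 0.0118). HB replicate 1 held 2495 CPM and HB replicate 2 only 399.6 CPM, and Fasn lost its call without HB replicate 1 (log2 change 1.13, adjusted p = 0.0661). Fads2 rose by 3.58, Cyp51 by 3.03, Plin2 by 2.58 and Sdha by 2.58, and each was called with any 1 library left out. Sqle rose by 3.00 and lost its call without HB replicate 1 (adjusted p = 0.0549). Pnpla3 was called at 4.02, but HB replicate 2 (2.33 CPM) lay below both HF libraries, and its change was -0.35 without HB replicate 1.

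Of 24 measured members of the cholesterol synthesis list 21 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 change of 2.08. The camera adjusted p was 1.81e-19 with the preset correlation, and the adjusted p = 0.565 with an estimated correlation. Of 22 members of the fatty acid synthesis list 14 rose and 1 fell (17 and 1 adjusted over the list alone; median 1.94; camera adjusted p = 3.46e-07, adjusted p = 0.565 with an estimated correlation). The respiratory chain list had 24 higher and 0 lower of 77 (27 and 0 adjusted over the list alone; median 0.66; camera adjusted p = 4.08e-07, adjusted p = 0.635 with an estimated correlation). Male-biased genes that depend on growth hormone, such as Mup15 (4.34) and Cyp4a12b (2.43), whose near-identical relatives make their counts uncertain, had 12 higher and 1 lower of 22 (15 and 1 adjusted over the list alone; median 1.48). Translation factors, lipid droplet, fatty acid oxidation, NRF2 target, ribosomal protein, plasma protein, macrophage and red blood cell lists were also called higher. The ribosomal protein median was 0.41, against 0.11 with total counts. The clock and neutrophil lists were called lower. Of 19 clock genes 4 were lower (Per2 -1.60, Per1 -1.17, Ciart -1.90 and Usp2 -1.13) and 0 higher (6 and 1 adjusted over the list alone), with a median of -0.76. Of 5 neutrophil markers 4 were lower and 0 higher (4 and 0 adjusted over the list alone), with a median of -1.85. In all 14 lists were called by camera, and 0 of them with an estimated correlation or with fry.

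With a length trend removed the ribosomal protein (adjusted p = 0.328) and clock (0.0561) lists lost their calls. Some list calls rested on single mRNA libraries. Without HB replicate 2 the ribosomal protein (adjusted p = 0.675), red blood cell (0.110) and neutrophil (0.165) lists lost their calls. Without HF replicate 2 the fatty acid oxidation (0.136), NRF2 target (0.0775) and neutrophil (0.315) lists did, and without HB replicate 1 the clock list (0.0509). Cholesterol synthesis, fatty acid synthesis and the respiratory chain were called with each library left out. The size was less stable: the median of the 46 cholesterol and fatty acid synthesis members was 2.00, but 1.11 without HB replicate 1 and 2.50 without HB replicate 2. Of the clock genes named as lower, Per2 kept its call with each mRNA library left out, and Usp2 with only 1 of them left out. Per1 lost its call without HF replicate 1 (0.0978), HF replicate 2 (0.0780) or HB replicate 1 (0.0795), and Ciart without HB replicate 1 (0.0723).

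**Figure D2:**
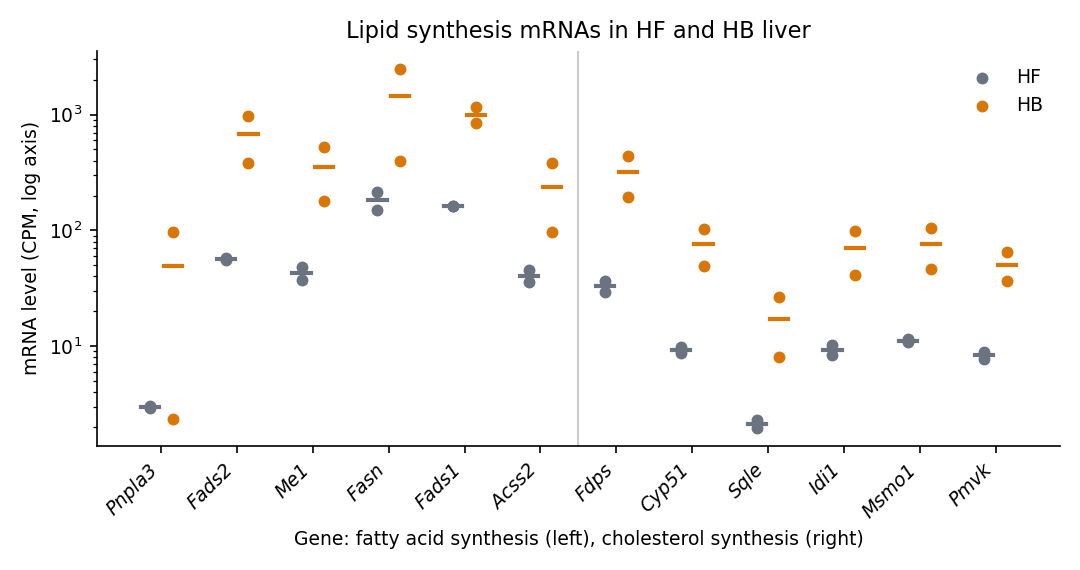
Levels of 6 fatty acid synthesis and 6 cholesterol synthesis mRNAs in CPM on a log axis; points are the libraries of HF and HB (2 each) and bars their means. Both HB libraries lay above both HF libraries for each gene but Pnpla3, and the HB libraries lay far apart in some, as in Fasn with 2495 and 399.6 CPM.

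Gnmt rose from 441 ± 121 to 1744 ± 625 CPM (log2 change 1.96, adjusted p = 0.00725), and it was called with each mRNA library left out. Pemt rose by 1.35 (adjusted p = 0.0128) and lost its call without HF replicate 1 (0.157). Bhmt (0.39) and Mat1a (0.00) were not called. In the list of betaine and one-carbon enzymes 6 of 32 rose and 0 fell (6 and 0 adjusted over the list alone), and the camera adjusted p was 0.0817. In the planned 7-library fit the same list was called higher (camera adjusted p = 0.0251, 0.424 with an estimated correlation). That call was lost without HF mRNA replicate 2 (0.190), HB mRNA replicate 1 (0.0552) or replicate 2 (0.0639), and HF ribosome-bound replicate 1 (0.0821) or replicate 2 (0.0814). Among genes that write, erase or read m6A, Fto, a demethylase, rose by 1.21 (adjusted p = 0.0201), but was not called without HF replicate 1 (0.186), HF replicate 2 (0.104) or HB replicate 1 (0.0771). Zc3h13, a part of the methylating complex, had a log2 change of -1.64 (adjusted p = 0.00751; 0.0531 without HB replicate 1), and the m6A reader Ythdc1 one of -1.31 (0.101 without HF replicate 1). The catalytic pair Mettl3 (0.03) and Mettl14 (-0.58) and Wtap, Alkbh5, Ythdf1, Ythdf2 and Ythdf3 were not called. The m6A list had 1 member higher and 3 lower of 21 (1 and 3 adjusted over the list alone; camera adjusted p = 0.305). The largest falls included Gadd45b (-4.13; adjusted p = 0.116 without HB replicate 1), a stress-induced gene, Il1r1 (-2.97), the interleukin-1 receptor, and Cyp2b13 (-3.01), a female-biased cytochrome. Srebf1, Ppara and Cyp7a1 were not called.

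The second comparison asked which mRNAs differ in level between diets in the ribosome-bound libraries. This level also follows total mRNA, so it is not a measure of binding alone. Most cholesterol and fatty acid synthesis mRNAs had higher levels in the HB library than on average in HF. With the HB pair summed this arm is 1 library, assumed to vary like the others, so the p values that follow do not measure spread within HB. The median log2 changes were 1.78 over 24 and 2.06 over 22 genes, and 1.84 and 2.06 with genes at 0 set to their bound. Total mRNA of these lists was higher too, and the median log2 change of their translation ratio was 0.16 over both lists together. Fdps passed the threshold in the 7-library fit, at 127 ± 59.0 CPM in HF (SD, n = 2) and 1367 CPM in HB (n = 1; log2 change 3.43, edgeR adjusted p = 0.0291), and with the ribosome-bound libraries alone edgeR called 0 genes. Its adjusted p was 0.108 without either HF mRNA library and 0.102 without either HB mRNA library. Fasn showed 134 ± 14.3 CPM in HF and 1327 CPM in HB and was not called (adjusted p = 0.137). Camera adjusted p values were 0.000383 for cholesterol synthesis, 0.0155 for fatty acid synthesis and 0.000475 for the respiratory chain, each 0.870 with an estimated correlation. Without HF ribosome-bound replicate 2 fatty acid synthesis and the respiratory chain were not called (0.476 each), nor was the respiratory chain without HF ribosome-bound replicate 1 (0.374). Within these lists 4 and 0, 1 and 1, and 3 and 2 members were called higher and lower (5 and 0, 2 and 1, and 1 and 0 adjusted over the list alone).

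The 7-library fit called 1459 ribosome-bound genes, 961 higher and 498 lower in HB. Of these, 886 had at most 3 reads in both HF libraries and 428 had at most 3 in the HB library. Examples with 0 reads in HF were Acss2, which makes acetyl-CoA from acetate (1252 reads in HB, at least 167-fold higher), and the interferon regulator Irf1 (676 reads, at least 90.4-fold higher). Notch1, a receptor for cell fate signals, had 0 reads in HB and was at least 264-fold lower there. In simulated libraries with this spread the same fit called 736 unchanged genes, so the count does not measure how many genes changed. The spread of log2 differences between the HF ribosome-bound replicates (SD 2.67) was no smaller than that between an HF and an HB library (2.36 to 2.52). The fit of the ribosome-bound libraries alone, with 0 calls by edgeR, had 350 genes at an unadjusted p under 0.05. Leaving out HF or HB mRNA replicate 1 or 2 also gave 0, with 1923 to 2239 at an unadjusted p under 0.05. With HF ribosome-bound replicate 1 or replicate 2 left out far more genes were called. No ribosome-bound group then had a replicate and the spread came from the mRNA libraries alone, so those counts do not measure change with diet. On the 7 libraries DESeq2 called 2852, limma on log2(RPKM + 0.1) 1256 and limma voom with quality weights 1019. The balance of directions moved with the method and the filter: 65.9% of the edgeR calls were higher in HB, against 44.7% with DESeq2 and 54.8% with a mean of at least 5 CPM. On simulated libraries DESeq2 called 4389 unchanged genes here, so its count and balance are not controlled.

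The third comparison asked whether the share of an mRNA that is bound to ribosomes, the translation ratio, changed with the diet. Gnmt and Pemt, whose total mRNA rose, were not called in the ribosome-bound libraries, at 208 ± 60.1 CPM in HF (SD, n = 2) and 91.4 CPM in the single HB library for Gnmt, and 138 ± 10.9 and 66.5 CPM for Pemt. With 1 HB ribosome-bound library the tests of the ratio borrow their spread from the other groups. On that footing the translation ratios of both genes had log2 changes of -3.16 (adjusted p = 0.0487) and -2.41 (adjusted p = 0.0319). Fatty acid oxidation and plasma protein mRNAs were lower in ratio, with medians of -0.69 over 33 and -0.70 over 32 genes (-0.73 and -0.70 with genes at 0 set to their bound). Their camera adjusted p values were 0.00647 and 0.00686, each 0.756 with an estimated correlation. The first list had 1 member called higher and 1 lower by edgeR (1 and 1 adjusted over the list alone), and the second 0. Without HF ribosome-bound replicate 1 neither list was called (0.475 each), nor without replicate 2 (0.0501 for fatty acid oxidation and 0.228 for plasma proteins).

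In all 1328 genes were called, 820 higher and 508 lower (61.7% higher, against 49.2% with DESeq2 and 49.0% with a mean of at least 5 CPM), and 1227 of them were also called in the ribosome-bound comparison. DESeq2 called 2205, but also 3229 unchanged genes on simulated libraries, so its count and balance are not controlled. On the real libraries limma voom with quality weights called 895, and limma on log2(RPKM + 1) called 0, with 2240 at an unadjusted p under 0.05. In edgeR, leaving out HF or HB mRNA replicate 1 or 2 gave 0 calls, with 1762 to 2170 at an unadjusted p under 0.05. The adjusted p of Gnmt then lay between 0.176 and 0.188, and that of Pemt too. Over the alternatives it ran from 6.81e-05 to 0.613 for Gnmt and from 3.10e-08 to 0.613 for Pemt. Gnmt was also lost without HB ribosome-bound replicate 1 (0.0513). Leaving out HF ribosome-bound replicate 1 or replicate 2 gave far more calls, but with the spread taken from the mRNA libraries alone. The simulation cannot tell whether the edgeR count is controlled on the real libraries. Total counts in place of TMM moved the median change of the ratio over all genes by 0.24. Among lists not called in this contrast, ribosomal proteins also had a low median, at -0.87 with genes at 0 set to their bound.

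The fourth comparison set ribosome-bound against total mRNA within each diet. Ribosomal protein mRNAs had far fewer reads in the ribosome-bound than in the mRNA libraries, relative to other genes. In HF 73 of 79 were called lower and 0 higher (77 lower and 0 higher adjusted over the list alone), with a median log2 ratio of -5.00 (-4.97 with genes at 0 set to their bound), and camera gave an adjusted p = 3.03e-27. In HB 68 were lower and 0 higher (79 lower and 0 higher adjusted over the list alone), with a median of -5.73 (-5.70 with bounds) and a camera adjusted p = 1.78e-18. With an estimated correlation the adjusted p was 0.906 in HF and 0.832 in HB. The median of all genes was -0.56 in HF and -0.71 in HB. Total counts moved it by 0.15 and 0.37, and left the ribosomal protein medians at -4.85 and -5.35. With a length trend removed the median of all genes turned to 0.86 in HF and 0.35 in HB, while the ribosomal protein medians were -3.66 and -4.71, with 66 genes lower and 0 higher in each diet. In HB fatty acid oxidation, NRF2 target and pericentral genes were also lower by camera (adjusted p = 0.0104 each, 0.832 each with an estimated correlation). Each of these 3 lost its call without HB mRNA replicate 2 (0.0591), and fatty acid oxidation and pericentral genes did without HF ribosome-bound replicate 1 (0.211 and 0.140) or replicate 2 (0.209 and 0.143).

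In HF 495 genes were called higher and 3123 lower, and in HB 803 and 2781. This balance was not stable to transcript length: 13.7% of the calls were higher in HF and 22.4% in HB, against 54.1% of 5584 and 47.8% of 4385 with a length trend removed. Low ratios in HF included genes with 0 ribosome-bound reads, whose values are bounds and cannot be ranked: Ddit4 (at least 149-fold lower), Rxrb (136), Jun (127), Pex11a (125) and Taz (113). Among genes with reads, Rps28 was 1966-fold lower (95% interval for counting error 353 to 77674, from 1 read). High ratios included Rhox8, at 505-fold (139 to 4178), and the log2 ratios of Aqp7 (6.94), Rab3c (6.70) and Cplx2 (6.37). With edgeR, leaving out HF mRNA replicate 1 or 2 gave 0 calls in HF (3570 and 3527 at an unadjusted p under 0.05). Leaving out HF or HB mRNA replicate 1 or 2 gave 0 in HB (3819 to 4063 at an unadjusted p under 0.05). DESeq2 on the 7 libraries called 4036 in HF and 4622 in HB. With HF ribosome-bound replicate 1 or replicate 2 left out far more were called in both diets, but the spread then came from the mRNA libraries alone.

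**Figure D3:**
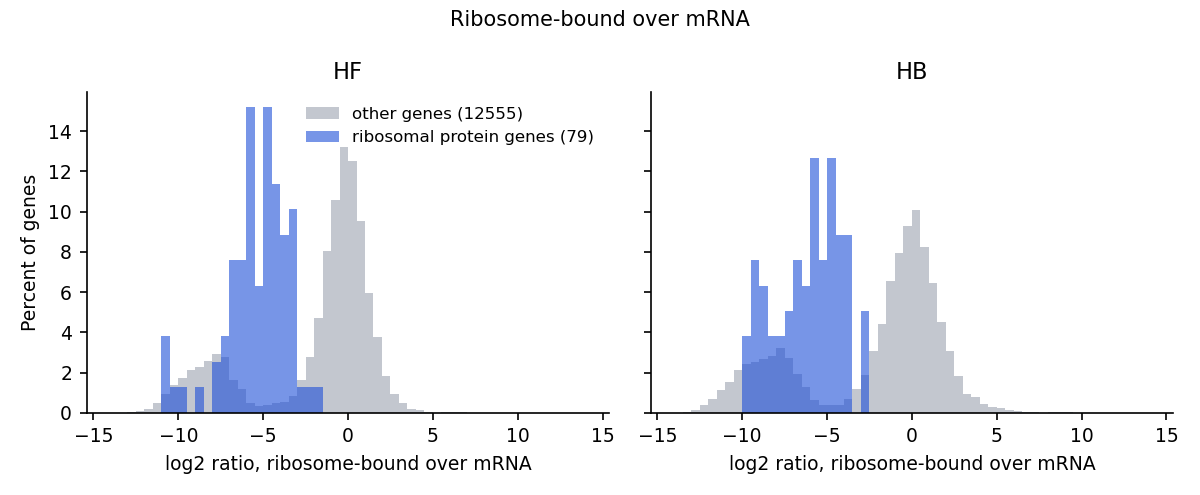
Share of genes (percent) by log2 ratio of ribosome-bound over total mRNA in HF and HB, for 79 ribosomal protein genes and all other genes tested. The ribosomal protein genes center at -5.00 in HF and -5.73 in HB, and the smaller hump of other genes at low ratios holds genes with few or no ribosome-bound reads.

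The m6A libraries asked where methylated sites lie and whether they differ with diet. The m6A writer gene Mettl3 carried peaks in both HB libraries and in neither HF library, but at different places. In HB replicate 1 the strongest lay on chromosome 14 from 52307570 to 52307782 (mm10), with a fold enrichment of 41.4, and in HB replicate 2 from 52304019 to 52304218, with 10.6. Ppara, the fatty acid sensor, carried peaks in all 4 libraries. Its strongest peak in HF replicate 1 (chromosome 15, 85800981 to 85801611, fold enrichment 22.3) overlapped the strongest of HF replicate 2 and HB replicate 2. Bhmt, Gnmt, Mat1a and Mettl14 carried none in any library.

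Peaks had median lengths of 215 to 230 bp, and 89.2% to 91.9% of them lay inside spans of protein-coding genes. Libraries shared few peaks, and no more within HB than between diets. On average 22.4% of peaks were met by a peak of the other library within HF, 18.6% within HB, and 17.7% to 19.6% between diets, where peaks moved at random within genes met 3.83% to 4.50%. In each library 63.1% to 70.4% of peaks were met in none of the other 3, and 7.39% to 8.64% in all of them.

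**Figure D4:**
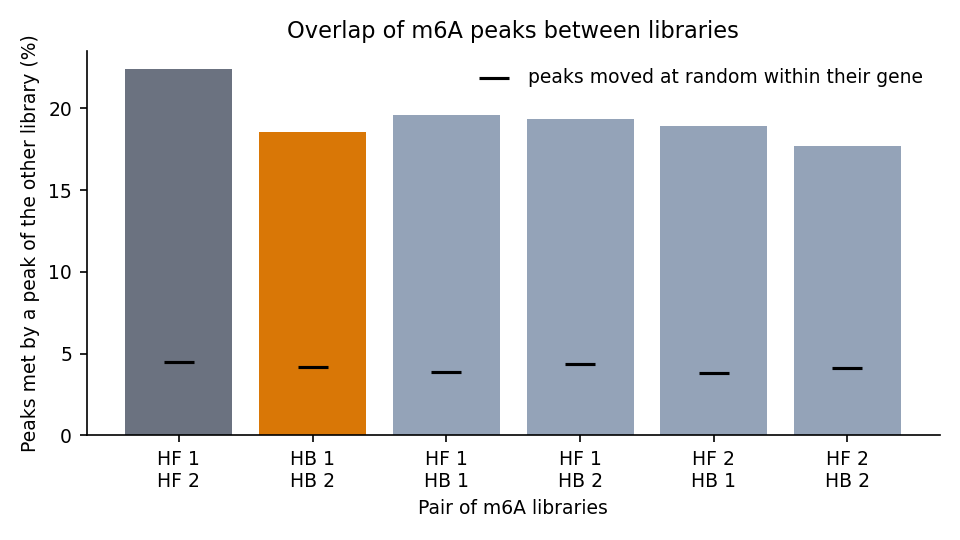
Percent of m6A peaks met by a peak of the other library, as the mean over both libraries of a pair. Bars are the pair within HF, the pair within HB and the 4 pairs between diets. Black marks are the percent of the first library's peaks in genes that were met when the second library's peaks were moved at random within their gene. The pair within HB (18.6%) lies among the pairs between diets (17.7% to 19.6%).

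A total of 416 genes carried peaks in both HB libraries and neither HF library, and 467 in both HF and neither HB, which is 883 genes split by diet. The other ways to pair the libraries split 704 and 867 genes. With an overlap of at least 50% of both peaks these sets held 65 HB and 169 HF genes. Leaving out 1 library of the other diet, which loosens the criterion, gave 999 HB genes without HF replicate 1 and 1033 without HF replicate 2, and 1071 HF genes without HB replicate 1 and 1193 without HB replicate 2. Among the HB genes with the highest enrichment were Plagl2, a zinc finger factor, Rnf41, a ubiquitin ligase, and C330021F23Rik. The peaks of C330021F23Rik in both HB libraries overlapped (chromosome 8, 3584017 to 3584421 in HB replicate 1, fold enrichment 22.5). The strongest peaks of Plagl2 and of Rnf41 lay at different places in the HB libraries and did not overlap. Among the HF genes were Nes, Avpr1a, a vasopressin receptor, and Twistnb (chromosome 12, 33437635 to 33438131 in HF replicate 1, fold enrichment 31.3).

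These gene sets were compared with mRNA, ribosome-bound mRNA and translation ratio between diets, to ask whether genes with diet-specific peaks change. In the fit of the 4 mRNA libraries 33 genes with HB-only peaks were higher and 25 lower of 300, and 51 genes with HF-only peaks were higher and 27 lower of 396, against 1446 higher and 1294 lower of all 12817 genes tested. Of 4562 genes with peaks in all 4 libraries, 339 were higher and 566 lower. Their median transcript length was 3845.5 bp, against 2762 bp for all genes tested, so this set differs from the others in length as well as in peaks. The HF-only genes called in mRNA included Acsl5, which activates fatty acids (2.40, adjusted p = 0.00507), Angptl8, an inhibitor of lipoprotein lipase (-1.65, adjusted p = 0.00593), and Tmem97 (2.00, adjusted p = 0.00423). Each was called in all 15 alternatives of that fit. Camera called 0 of the 3 sets in any contrast, and fry 0; adjusted p values ran from 0.0935, for genes with peaks in all 4 libraries in mRNA, to 0.962. That set had a median change of -0.07 and an unadjusted p of 0.0312, and it was called without HB mRNA replicate 1 (adjusted p = 0.00174), over a range of 0.00174 to 0.610 with 1 library left out.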

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

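Chosen after the result was seen were the tests of 1 HB library read 2 times, of 1 HB mRNA library alone, of fasting, of pyrimidine-tract starts, and of loss from all genes with pseudogenes, as was the fit with a length trend removed.

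The change with diet differed between ribosome-bound and total mRNA for 1328 genes, by a test of that difference (edgeR's interaction contrast, Benjamini-Hochberg adjusted). Of these, 1227 were also called between diets in the ribosome-bound libraries, but both contrasts use these same libraries, so the overlap does not tell which side the difference came from. Of the 1328, 767 had at most 3 reads in both HF ribosome-bound libraries and 405 had at most 3 in the HB one.

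The first pattern weighed is that ribosome-bound genes called between diets mostly had 0 to 3 reads in the libraries of 1 diet. After the HB reads were thinned to the smaller HF total, 99.8% of such genes called higher in HB (884 of 886) kept more than 3 reads. At the HF depth these genes would thus still have been detected. The fit had already scaled for library size, and they had a median of 133 HB reads, so their choice largely set this outcome. Random loss of mRNAs from these libraries, unrelated to diet, stays open and is a candidate explanation: over 7922 genes the odds ratio of detection within HF was 0.963 times the mean of those between HF and HB (95% interval over genes 0.818 to 1.17), so HF replicates shared no more missing genes than libraries of different diets. Stratified by mRNA level, the odds ratios were 3.72 within HF and 3.34 and 4.38 between HF and HB. In all 3 libraries 221 genes had at most 3 reads. Libraries thus shared missing genes across diets, which argues against loss with even odds for genes of like mRNA level. Only a loss that strikes some genes more than others stays open. Whether the HB pair is 1 library read 2 times was not decided: the count of 0 genes with 0 reads in 1 run and over 20 in the other, against 2798 in the HF pair, is the observation that raised the question. A change of ribosome binding with diet stays open too, and was not tested apart from these.

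The second pattern is that fatty acid and cholesterol synthesis mRNAs were higher in HB. Removing a length trend left the median of the 46 members at 2.06 (2.00 before), which argues against length bias as the whole cause. With HB replicate 1 left out the median was 1.11, with quartiles 0.534 and 1.92; 42 of 46 members were positive and 18 were called, so 1 library alone was not the whole cause, although this lies only just above the bound of 1 set for it. Feeding state at collection cannot be told apart from diet here, since 14 fasting-induced genes had a median of -0.19, with 8 negative and 6 positive. An effect of betaine is a hypothesis that stays open beside it.

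The third pattern is that ribosomal protein mRNAs were far lower in ribosome-bound than in mRNA libraries of both diets. The 15 genes with no pseudogene named after them had a median log2 ratio of -4.98 in HF, against reads shared with pseudogenes, but 8371 of 10622 pseudogenes carry predicted-gene names, so this absence is weak evidence. Other genes with at least 2 named pseudogenes had a median of -0.40, against loss of reads from all such genes. Genes matched on length and mRNA level lay 4.67 above the list, against short transcripts. Of mRNAs known to start with a pyrimidine tract, 16 others had a median of -0.00347, against a hold on all such mRNAs; low translation of ribosomal proteins alone and a loss specific to them in preparation stay open, as untested.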

How the results depend on the processing

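Added after the data were seen were the fits with the HB ribosome-bound runs as 2 libraries, voom quality weights, total counts, the length trend, the crossed pairing, and all alternatives within the fit of the 4 mRNA libraries. Where a count or call moved below, the cause was not tested unless stated.

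Counts of called genes moved as follows, from 0 in mRNA (1647 at an unadjusted p under 0.05), 1459 in ribosome-bound mRNA, 1328 in the translation ratio, and 3618 and 3584 in the ratio within HF and HB. DESeq2 gave 1133, 2852 and 2205 for the first 3. The mean of at least 5 CPM gave 913 ribosome-bound, 816 ratio, 1405 HF and 1700 HB calls, with fewer genes tested. Limma on log2(RPKM + 1) gave 815 ribosome-bound and 0 ratio calls. Only the libraries compared gave 2740 mRNA, 0 ribosome-bound and 8314 HB calls. That last HB fit held 2 mRNA libraries and 1 summed ribosome-bound library, so its spread came from the HB mRNA pair alone. Like the fits without an HF ribosome-bound library, it does not allow for the spread of ribosome-bound mRNA. Its count is therefore not comparable with that of the planned fit. The HB runs as 2 libraries gave 131 mRNA, 2419 ribosome-bound, 2053 ratio and 5428 HB calls. Voom quality weights gave 881 mRNA calls, and removing the length trend gave 5584 HF calls, 3021 higher and 2563 lower, and left 47.8% of the HB calls higher, against 22.4%. Leaving out 1 library gave 0 to 2705 in mRNA, 0 to 4966 in ribosome-bound mRNA, 0 to 4859 in the translation ratio, 0 to 7856 in HF and 0 to 8191 in HB.

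In the fit of the 4 mRNA libraries the count stayed within 1.5 times of 2740 in each alternative with all libraries (2431 to 3603), and leaving out 1 library gave 776 to 3024. Total counts gave 25.2% higher among the calls, against 52.8%. Of 136 named genes called there, 53 were called in every alternative that tested them, which was at most 15.

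Whether replicate numbers are paired was not decided. The correlation of replicate differences was 0.113 between HF mRNA and HF ribosome-bound libraries, 0.041 between those of HB, and -0.124 between HF and HB mRNA. Such a check can miss a pairing. The SD of log2 differences was 2.67 in the HF ribosome-bound pair, 0.19 in the HB one and 0.43 in the HF mRNA pair. With the replicate number as a block there were 0 ribosome-bound, 0 translation ratio and 0 HB calls, and with a block per diet 0 translation ratio, 0 HF and 0 HB calls, by edgeR. At an unadjusted p under 0.05 the block gave 2255, 2210 and 4473, and the block per diet 874, 1514 and 1919. The crossed pairing gave 0 mRNA calls in the 7 libraries and 3407 in the 4. The block raised the called lists from 2 to 4 in the translation ratio.

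Camera with an estimated correlation called 0 lists in mRNA, ribosome-bound mRNA, the translation ratio, both ratios within diets and the 4 mRNA libraries. Fry called 1, 0, 0, 17, 22 and 0. Leaving out 1 library gave 9 to 17, 1 to 3, 0 to 6, 1 to 2, 1 to 6 and 11 to 18 lists.

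The set of genes with m6A peaks in all 4 libraries had a camera adjusted p of 0.0223 in mRNA with the 50% of peaks of highest fold enrichment, and 0.00174 to 0.610 with 1 library left out (0.000464 to 0.827 in the 4 mRNA libraries). Peaks met fell to 20.6% within HF, 15.0% within HB and 15.8% between diets with those peaks, and to 16.0%, 12.4% and 12.6% with an overlap of 50% of both. Peaks inside protein-coding spans moved to 91.3% in HF replicate 2, 89.3% in HB replicate 1 and 88.5% in HB replicate 2. A minimum fold enrichment of 4 was not run, since each peak passed it.

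Some named genes changed sign. Removing the length trend moved the median of all genes in the ratio in HF from -0.56 to 0.86, so sign changes there follow the bulk and do not set these genes apart. The log2 ratio became 0.46 for Dgat2, 0.17 for Slc27a5, 0.053 for Fabp1, 0.42 for Gc, 0.49 for F2, 0.035 for Serpina3n, 1.32 for Mat1a, 0.76 for Pemt and 0.59 for Ppara, and only that of Mat1a lay above the new median. With 1 library left out, Ccl5 ran from -1.37 to 9.65 between diets in ribosome-bound mRNA, and in the ratio in HF Mettl3 ran from -4.14 to 2.11 and Fto from -1.32 to 0.89; the reversals came without HF ribosome-bound replicate 2. Pnpla3 ran from -0.35, without HB mRNA replicate 1, to 4.98. Of the other values of named genes outside the 4-library fit, 9045 stayed called in the same direction or stayed uncalled, with either sign, 2446 lost a call and 547 gained one. Of 886 ribosome-bound genes called higher in HB with at most 3 reads in both HF libraries, 884 kept more than 3 HB reads after thinning. How these genes were chosen largely set this outcome.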
